A study of Synechocystis sp. PCC 6803 with 16 samples.

How the data were processed

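Total RNA of the cyanobacterium Synechocystis sp. PCC 6803 was compared on 16 spotted 2-colour DNA arrays. Per the labels' protocols, cells grew in light at 32 °C in buffered medium under 3% CO2, and inorganic carbon was then limited by aerating with air alone. Culture aliquots of 100 ml were stopped in cold phenol and ethanol, 16 µg of total RNA was copied into aminoallyl cDNA, and dye was coupled afterwards. Per the labels, channel 1 of each array held RNA taken 60, 180, 200, 360 or 720 min after the switch, and channel 2 held RNA of 0 min. The labels give 3 arrays each for 60, 180, 360 and 720 min and 4 arrays for 200 min. They do not say whether arrays of 1 time came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

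Per the labels' protocols, the authors quantified the images with GenePix Pro 4.1, made quality control in that software and stored the data in Acuity 3.1. The authors deposited 1 log2 ratio per spot for 12288 numbered spots and 16 arrays. The log base follows from the values, since weak spots repeat exact log2 values of ratios of small whole numbers. Direction, dyes, background handling, the rule that left spots blank and any normalization between the dyes are not given in the sources used here. Signs are therefore those of the deposited values. If the values are channel 1 over channel 2, a positive value means more RNA after the switch. The direction was to be judged from genes of inorganic carbon uptake, but the deposited table does not pair spot numbers with genes, and 0 spot identifiers matched the gene table used here (assembly ASM28445v1). The 21 lists of 301 genes fixed in advance, and the single genes named in advance, were therefore not tested. All columns of per-sample values were used.

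The medians of the deposited log2 ratios over spots were −0.13, 0.09 and 0.10 for 60 min replicates 1 to 3, −0.08, −0.07 and 0.03 for 180 min, −0.05, −0.26, −0.03 and −0.47 for 200 min replicates 1 to 4, −0.01, 0.08 and 0.19 for 360 min, and 0.01, 0.32 and 0.21 for 720 min. By a rule written before the data were examined, every array was centred on its median over positions, with copies averaged as described below. The rule applied because at least 1 of those medians lay more than 0.1 from 0, such as −0.44 for 200 min replicate 4. Each change is thus relative to the median position of its array.

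Values repeated along the spot numbers at a distance of 4096 (mean correlation 0.74 over the 16 arrays) and 8192 (0.65), and the next best distance reached 0.21. The spots were therefore read as 3 copies of 4096 positions, and copies were averaged per array. A position is written as P and its number among the first 4096 spots. Which positions are controls is not known here, so none were left out. Spots near background were recognised by ratios that equal the quotient of 2 whole numbers up to 10 at the deposited 3 decimals. Positions with over 0.5 of their spots at such ratios are called near background (455 positions), those with at most 0.1 bright (3102 positions), and the others dim (539 positions). This grouping was chosen after the data were seen. Blank spots made up 7.31% to 21.8% of an array, and 3215 positions had a value on all 16 arrays. The number of arrays limits the precision, and signal over background is known only through this grouping. The grouping cannot flag a ratio over 10-fold, so a large ratio with 1 channel near background is not recognised.

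Arrays of 1 time were compared before averaging. Over 2390 bright positions with all copies, the spread of the difference between 2 arrays was divided by the noise that their copies predict. Simulated pure noise gave a ratio of 1.09. Replicates 1 and 2 gave 1.13 at 60 min, 1.13 at 180 min and 0.875 at 360 min, whereas every other pair of the same time gave at least 1.46. The comparison says nothing of weak positions. Each of these 3 pairs, with a ratio of at most 1.25, was averaged and counted as 1 sample. This left 2 samples at 60, 180 and 360 min, 4 at 200 min and 3 at 720 min. Replicates 1 and 2 were also the closest pair at 200 min (1.46) and at 720 min (1.79) but stayed separate samples. Whether they came from separate cultures is not known, so n may be too high at these times. The design fixed in advance counted 16 arrays, and that count is given as an alternative.

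The 13 samples entered 1 limma model (limma 3.58.1 in R 4.3.3) with a mean per time, empirical Bayes moderation without trend and Benjamini-Hochberg adjustment over all positions tested, with a threshold of 0.05. A position needed 2 values at each time compared. Each time was tested against 0, 5 differences between times were tested, and moderated F tests asked for any difference among the 5 times and for any change. The ratio against 0 leaves out the spread of the 0 min RNA itself. To show what that can do, 20 sets of unchanged samples were simulated against 1 shared 0 min RNA that varies as much as the samples do; the real spread of that RNA is not known. Recovery was checked on simulated values for 4096 positions with the real spread and no shared 0 min RNA. All changed positions were bright, so the rates do not cover dim and near-background positions. A change of 0.5 was recovered at 36%, 40%, 64%, 30% and 64% of changed positions at 60, 180, 200, 360 and 720 min. A change of 1 was recovered at 76%, 92%, 96%, 90% and 90%.

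Replicate numbers occur at every time. The numbers were not taken to pair samples, and replicate number as a block is given as an alternative. Named positions follow a rule written before the data were examined. Per time, it takes the 6 largest positive and the 6 largest negative mean log2 ratios among positions past the threshold. A position must be measured on every array of that time, with the same sign on each. The rule also takes the 6 largest ranges in the F test. Because the sources used here give the positions no gene names, only 2 of each sign are printed. These are the ones that the rule chose at the most times and then the largest. Alternatives fixed before the data were examined were values as deposited, a common scale for the arrays, positions present on all arrays, the median of copies, a robust prior, replicate number as a block, an added size limit, a fit of the compared times alone and leaving out each array. The 16 separate arrays were the count fixed in advance, and averaging the repeat pairs was chosen after seeing the data. Alternatives chosen after seeing the data were bright positions only, positions not near background, single copies, copies centred separately and spots off small whole-number ratios. A fit with the 200 min arrays left out and leaving out both arrays of a repeat pair were also chosen then.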

Results

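The arrays followed transcript levels of Synechocystis sp. PCC 6803, a freshwater cyanobacterium that fixes CO2 by photosynthesis, after its cultures were moved from air enriched to 3% CO2 to air alone. The series asked how the cells respond to limitation of inorganic carbon (CO2 and bicarbonate). RNA taken 60, 180, 200, 360 and 720 min after the switch was compared with RNA of 0 min on the same array. Of the 16 arrays, replicates 1 and 2 at 60, 180 and 360 min differed by about the noise between copies over 2390 bright positions. Their ratios to that noise were 1.13, 1.13 and 0.875, against 1.09 for simulated pure noise. Each pair was counted as 1 sample. The 60 min pair was less alike elsewhere, with a correlation of 0.50 over all bright positions, below the 0.66 and 0.68 of replicate 1 with 180 min replicates 1 and 2, and a difference of 1.27 between medians near background. This gave n = 2 at 60 min, 2 at 180 min, 4 at 200 min, 2 at 360 min and 3 at 720 min. Replicates 1 and 2 were also the closest pair at 200 and 720 min, with ratios of 1.46 and 1.79, but stayed separate samples. Between 9613 and 11390 of the 12288 spots had a value on an array, and the spots were read as 3 copies of 4096 positions. The deposited values do not pair the positions with genes, so positions are given by number. Signs are those of the deposited log2 ratio after centring, since the labels do not settle which channel was divided by which.

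Few positions passed the test against 0 min at 60 and 180 min. At 60 min 10 of 3987 positions passed the threshold of the moderated test, 4 with a positive and 6 with a negative log2 ratio. At 180 min 53 of 3962 positions passed, 21 positive and 32 negative. In the same tests 635 positions at 60 min and 517 at 180 min had an unadjusted p under 0.05. The few calls at n = 2 thus do not show that few positions changed. The median size of the log2 ratio over bright positions was 0.17 ± 0.01 (SD, n = 2) at 60 min and 0.14 ± 0.02 (SD, n = 2) at 180 min. At 60 min 2 bright positions were at least 2-fold positive on every array and 4 at least 2-fold negative, and at 180 min 14 were positive and 5 negative by that measure. Unchanged samples that share a 0 min RNA gave a mean of 116 calls at 60 min and 113 at 180 min in simulation. Both observed counts lay below the lowest of 20 draws (53 and 57). The simulated covariance between 60 and 180 min (0.0979) also exceeded the observed 0.0649. The spread assumed for the 0 min RNA may thus be too large. So may the spread assumed for the early samples, which was shared over the 5 times. In the limma test of 180 against 60 min, free of a shared 0 min RNA, only 62 of 3889 positions had an unadjusted p under 0.05. Whether the early counts exceed no change stays open. The early counts depended on how arrays were counted and scaled. With 16 separate arrays 558 positions passed at 60 min and 429 at 180 min, and with the arrays brought to a common scale 644 and 911 passed. Without centring, the calls at 60 min were 7 positive and 3 negative. Without both arrays of the repeat pair the counts were 0 at 60 min (334 at an unadjusted p under 0.05) and 4 at 180 min. Without replicate 3 they were 22 and 15, and without replicate 1 the count at 60 min was 20.

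At 200 min 2062 of 4051 positions passed, 992 positive and 1070 negative. Bright positions gave 1749 of these calls, 759 positive and 990 negative, and the median size of the log2 ratio over bright positions was 0.34 ± 0.07 (SD, n = 4). At least 2-fold ratios on all 4 arrays were found at 84 bright positions with a positive and 114 with a negative sign. Simulated unchanged samples with a shared 0 min RNA gave a mean of 635 calls. Positions near background gave 142 of the calls, and all 142 were positive. Blank spots made up 17.8%, 12.8%, 8.91% and 21.8% of replicates 1 to 4 of 200 min, against a mean of 9.15% over the arrays of the other times. Values as deposited gave 566 positive and 1437 negative calls, so the balance of signs depended on centring. The fit of the 200 min arrays alone gave 1031 calls.

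At 360 min 1120 of 3926 positions passed, 481 positive and 639 negative, and at 720 min 1771 of 4039 passed, 790 positive and 981 negative. The simulated means for unchanged samples with a shared 0 min RNA were 109 and 372. The median size of the log2 ratio over bright positions was 0.31 ± 0.02 (SD, n = 2) at 360 min and 0.39 ± 0.05 (SD, n = 3) at 720 min. At least 2-fold ratios on every array were found at 62 positive and 108 negative bright positions at 360 min, and at 98 positive and 189 negative ones at 720 min. Among called bright positions at least 8-fold from 0, 16 were positive and 1 negative at 360 min, and 18 positive and 5 negative at 720 min. At least 4-fold from 0 were 26 positive and 11 negative at 360 min, and 29 positive and 56 negative at 720 min. Values as deposited gave 537 positive and 428 negative calls at 360 min and 1043 positive and 614 negative calls at 720 min. Without replicate 3 the count at 360 min was 547, without the repeat pair it was 663, and the fit of the 360 min arrays alone gave 339.

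**Figure D1:**
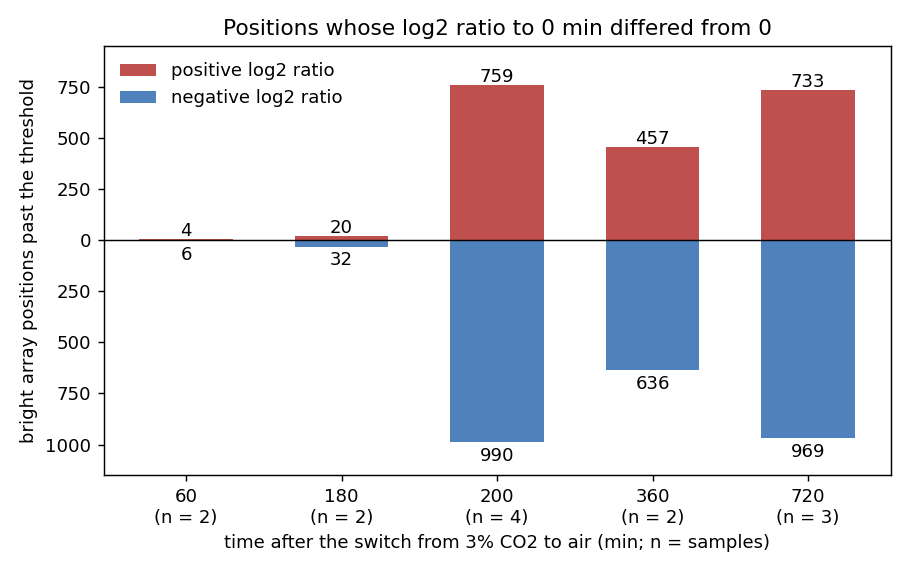
Number of bright array positions past the threshold (bars; positive log2 ratios upward from 0, negative ones downward) at each time after the switch, with the number of samples under each time. Calls numbered 4 and 6 at 60 min and 20 and 32 at 180 min, and at 200, 360 and 720 min there were 759 and 990, 457 and 636, and 733 and 969. Counts also depend on the number of samples, so they do not compare the size of the change between times. Simulated unchanged samples with a shared 0 min RNA gave means of 477, 73.7 and 265 bright calls at 200, 360 and 720 min. The excess of negative calls depended on centring. In a fit of bright positions alone, centred on their own median, the late calls were 927 and 974, 607 and 662, and 905 and 950.

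The positions called at 360 min and at 720 min were largely shared. Among 3101 bright positions tested at both times, 430 were positive at both and 615 negative at both, and 0 had opposite signs, against 108 and 199 for independent lists. Of the bright calls at 360 min, 95.6% had the same sign at 720 min. Unchanged samples against a shared 0 min RNA gave 23.4 and 23.8 shared positions in simulation, from shorter lists (means of 73.7 calls at 360 min and 265 at 720 min), and a share of 63.9% (52.0% to 80.3% over 20 draws). Part of the excess may come from the shared 0 min RNA, which could not be split. Of the 430 positive positions, 328 were also positive at 200 min, 16 at 180 min and 1 at 60 min. Their median log2 ratio was 0.03 at 60 min, 0.09 at 180 min, 0.49 at 200 min, 0.59 at 360 min and 0.69 at 720 min. Of the 615 negative positions, 391 were negative at 200 min, 17 at 180 min and 1 at 60 min. Their medians were −0.04, −0.08, −0.37, −0.70 and −0.82 in the same order. Calls of the opposite sign numbered 18, 3 and 3 in the positive set and 13, 1 and 2 in the negative set at 200, 180 and 60 min. The sets were chosen by their late calls, and through a shared 0 min RNA that choice can also pull the values at 60, 180 and 200 min the same way.

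Positions P3166 and P3672 had the largest positive log2 ratios that recurred. P3166 had a mean log2 ratio of 9.14 at 200 min (SD 1.11, n = 4, adjusted p = 1.02e-06), 7.85 at 360 min (SD 0.02, n = 2, adjusted p = 8.04e-05) and 8.60 at 720 min (SD 1.88, n = 3, adjusted p = 4.17e-06). At 60 and 180 min its means were −0.06 (SD 0.70, n = 2) and 0.63 (SD 0.54, n = 2), and neither passed the threshold. P3672 had means of 9.56 (SD 1.85, n = 4, adjusted p = 1.17e-06), 7.68 (SD 0.14, n = 2, adjusted p = 0.000142) and 8.0 (SD 1.08, n = 3, adjusted p = 1.10e-05) at 200, 360 and 720 min. Its means of 0.71 (SD 0.68) at 60 min, where the arrays of the repeat pair gave −0.10 and 2.47, and 0.38 (SD 0.15) at 180 min did not pass. The sign was the same on all 10 arrays of the 3 late times at both positions. Together with 3 other positions they made up 5 that were among the 6 largest positive ratios at 200, 360 and 720 min alike, with means from 6.07 to 9.56 at those times. Single arrays reached 10.7 at P3166 (720 min replicate 1) and 12.2 at P3672 (200 min replicate 3). The grouping by brightness cannot flag ratios over 10-fold. Whether 1 channel lay near background at these positions was not tested, so the sizes of their late ratios are uncertain.

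Positions P2056 and P3228 had the largest negative log2 ratios chosen at the most times. P2056 had means of 0.26 (SD 0.45, n = 2) at 60 min and 0.34 (SD 0.23, n = 2) at 180 min, which did not pass, then −1.43 (SD 0.28, n = 4, adjusted p = 4.62e-05) at 200 min, −2.77 (SD 0.17, n = 2, adjusted p = 1.69e-05) at 360 min and −4.48 (SD 0.37, n = 3, adjusted p = 8.91e-08) at 720 min. P3228 had means of −0.13 (SD 0.26) at 60 min and −0.47 (SD 0.04) at 180 min, which did not pass, and −3.90 (SD 1.08, n = 3, adjusted p = 0.000203) at 200 min. Its means at 360 and 720 min were −2.94 (SD 0.25, n = 2, adjusted p = 0.00529) and −3.55 (SD 1.22, n = 3, adjusted p = 0.000324). The call of P3228 at 360 min ended without replicate 3 (adjusted p = 0.0539) and without the repeat pair (adjusted p = 0.0685), with log2 ratios of −3.12 and −2.76, and also with copy 1 alone (−2.94, adjusted p = 0.0915). Of the negative positions chosen by the rule, 0 were among the 6 at 200, 360 and 720 min alike, and 3 were among them at both 360 and 720 min. P3228 had no value on 200 min replicate 4, so the rule could not choose it at 200 min. Its mean there lay further from 0 than that of P2245 (−3.39), which the rule chose.

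**Figure D2:**
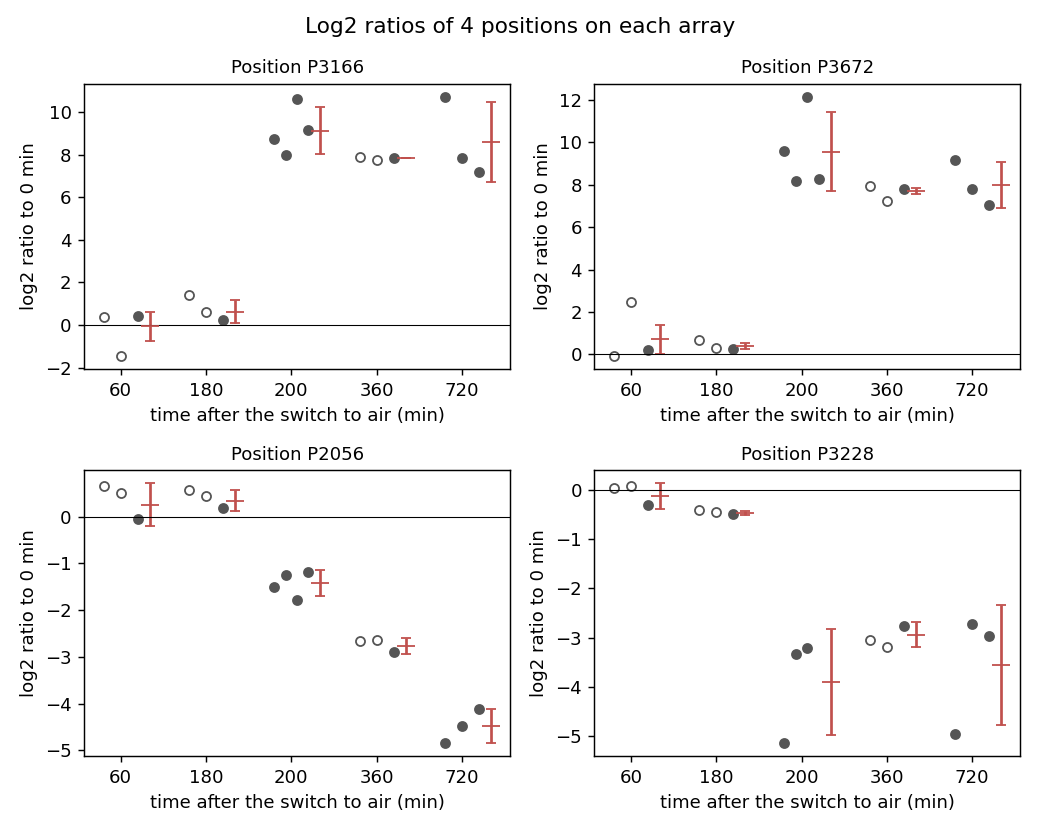
Log2 ratio to 0 min (vertical axis, median-centred) of 4 array positions at each time after the switch (horizontal axis, min), with each array as a point, open where 2 arrays were counted as 1 sample, and the mean ± SD of the samples in red. P3166 and P3672 lay above 7 on every array from 200 min on, and P2056 reached a mean of −4.48 at 720 min.

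The direct test of 180 min against 60 min called 0 of 3889 positions with limma, and 62 had an unadjusted p under 0.05. That is a share under 0.05, so this test may be too strict and the 0 does not show equal levels. Between 200 min and 180 min, which are 20 min apart, 707 of 3922 positions differed, 328 with a higher and 379 with a lower log2 ratio at 200 min. P3166 differed by 8.51 (SE 0.96, adjusted p = 0.000214), P3672 by 9.17 (SE 1.02, adjusted p = 0.000200), P2056 by −1.77 (SE 0.26, adjusted p = 0.00111) and P3228 by −3.43 (SE 0.74, adjusted p = 0.0131). The count was 344 without 180 min replicate 3, 373 without the 180 min repeat pair, 350 in a fit of these times alone and 1139 with 16 separate arrays. Values as deposited gave 207 higher and 429 lower.

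Between 360 min and 180 min 524 of 3835 positions differed, 236 higher and 288 lower at 360 min. P2056 was lower by −3.12 on the log2 scale (SE 0.30, adjusted p = 0.000201), whereas the difference of −2.48 at P3228 did not pass (SE 0.81, adjusted p = 0.0852). Without 180 min replicate 3 the count was 266, without 360 min replicate 3 it was 270, without the repeat pairs it was 245 and 330, in a fit of these times alone it was 164, and with 16 separate arrays it was 984. Without centring, 250 were higher and 200 lower.

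Between 720 min and 360 min 33 of 3888 positions differed, 9 higher and 24 lower at 720 min, and all 33 lay further from 0 at 720 min than at 360 min with the same sign. P2056 was among them, with a difference of −1.71 (SE 0.27, adjusted p = 0.0296). P3166 and P3672 differed by 0.75 (SE 1.01) and 0.32 (SE 1.08), and neither passed. The count fell to 0 without 360 min replicate 3, without the 360 min repeat pair or without any 1 of the 3 arrays of 720 min, where 250 to 315 positions had an unadjusted p under 0.05. It was 0 with the arrays on a common scale (116 at an unadjusted p under 0.05) and 169 with 16 separate arrays.

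Between 720 min and 60 min 1125 of 3940 positions differed, 486 higher and 639 lower at 720 min. All 4 named positions were among them, with differences of 8.66 at P3166, 7.30 at P3672, −4.74 at P2056 and −3.42 at P3228. Values as deposited gave 530 higher and 416 lower, and without the 60 min repeat pair the count was 690. Over the 5 times, 1326 of 3741 positions differed among times in the moderated F test, and 2186 of 3741 differed from 0 at any time, against a simulated mean of 854 for unchanged samples with a shared 0 min RNA.

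Across bright positions, which are not independent replicates, mean log2 ratios fell into an early and a late part of the series. Pearson's r was 0.78 between 60 and 180 min and 0.95 between 360 and 720 min, and the 200 min means had r = 0.73 with 360 min, 0.71 with 720 min and 0.40 with 180 min. Between 60 min and the times from 200 min on r was 0.29, 0.25 and 0.17. Without 60 min replicate 3 it was 0.154 with 360 min and 0.095 with 720 min, and without replicate 2 it was 0.103 with 720 min. Unchanged samples that share a 0 min RNA gave simulated values from 0.66 to 0.77 over the 10 pairs of times, with 0.71 for 360 and 720 min, 0.73 for 200 and 360 min, 0.77 for 200 and 720 min and 0.67 for 60 and 180 min. The covariance was 0.54 between 360 and 720 min and 0.42 between 200 and 360 min, against simulated values of 0.0984 and 0.0975. Between 60 and 180 min it was 0.0649, below the simulated 0.0979. The lowest correlation of any 2 arrays over bright positions was −0.08.

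**Figure D3:**
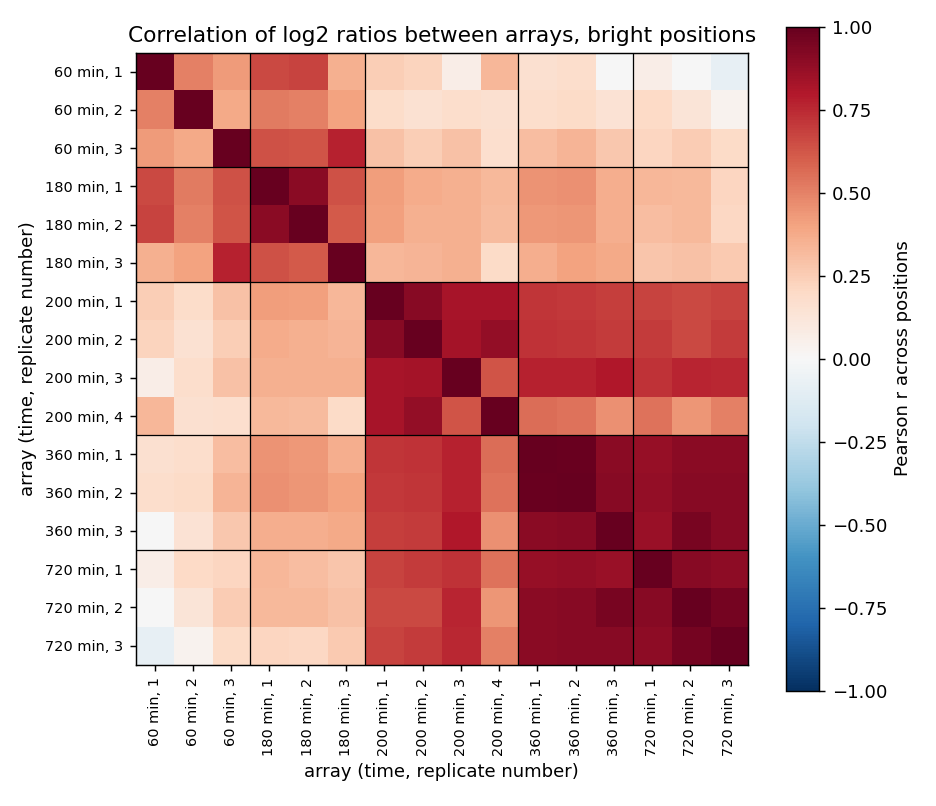
Pearson correlation of log2 ratios across bright positions for each pair of the 16 arrays (both axes, time and replicate number; colour scale from −1 to 1). Arrays of 360 and 720 min correlated at 0.86 to 0.95 with each other, and arrays of 180 and 200 min at 0.19 to 0.42.

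**Figure D4:**
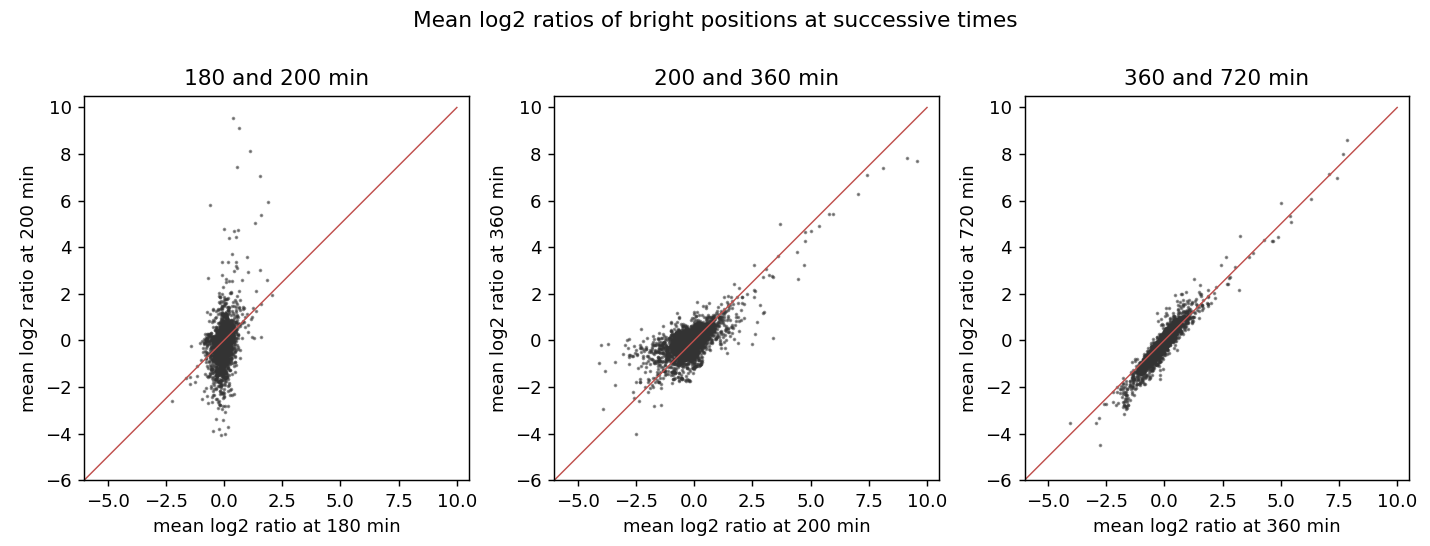
Mean log2 ratio of each bright position at 1 time (horizontal axes) against that at the next time (vertical axes), with the line of equality in red. The means of 180 and 200 min had r = 0.40, those of 200 and 360 min 0.73 and those of 360 and 720 min 0.95.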

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

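The tests of positions near background, of single 200 min arrays, of steady progress, of batch and of dim positions were chosen after the result was seen, while the counts of other splits were planned.

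Differences between times were large enough to pass a test of the difference itself in 5 counts. These were 707 positions between 200 and 180 min, 524 between 360 and 180 min, 33 between 720 and 360 min, 1125 between 720 and 60 min and 1326 among the 5 times. The highest count from another split of the same samples was 48 over 15 splits for 200 against 180 min, 0 over 3 splits for 360 against 180 min, 0 over 10 splits for 720 against 360 min and 0 over 10 splits for 720 against 60 min. In each of these only the real split, 1 in number, gave as many, and the splits are too few for a share under 0.05. For 180 against 60 min all 3 of the 3 splits gave as many as the real count of 0, again too few splits. For the 5 times, 1 of 100 random groupings, the real one, gave as many as 1326, and the highest other gave 307. The samples thus grouped by time more than under random groupings. Arrays of 1 time may share a culture, and a chance difference between cultures would give the same, so it is not excluded. For a change at any time, 1 of 100 sign patterns, the real one, reached 2186, with 698 as the highest other. Sign patterns take the samples as independent, whereas a shared 0 min RNA alone gave 774 to 918 calls in simulation, so that count of patterns was too low a bar and does not exclude chance. For 200 min against 0 the real sign pattern alone, 1 of 8, gave 2062 and the highest other 8, and for 720 min 1 of 4 gave 1771 and the highest other 0, too few patterns for a share under 0.05.

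The named positions differed between times by the same tests. P3166 differed by 8.51 between 200 and 180 min, 7.22 between 360 and 180 min and 8.66 between 720 and 60 min. P3672 differed by 9.17, 7.30 and 7.30 in the same order. P2056 differed by −1.77, −3.12 and −4.74 in that order, and by −1.71 between 720 and 360 min. P3228 differed by −3.43 between 200 and 180 min and by −3.42 between 720 and 60 min. Among 12 sets of values over the 4 arrays of 200 min, none passed Dixon's test, which few sets of 4 values can pass. Replicate 4 was still the most extreme array of that time in several measures, with 121 spots over 32-fold against 41 to 70, 22.7% of bright positions over 2-fold against 11.9% to 14.6%, and correlations of 0.44 to 0.56 with the 360 and 720 min arrays against 0.66 to 0.80.

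The samples of 200 min stood apart from those of 180 min although the times are 20 min apart. In a fit of bright positions only the count of differing positions was 849, and 673 of the 707 calls were at bright positions. This argues against positions classed as dim or near background as the source. The grouping cannot flag ratios over 10-fold, so bright positions with 1 channel near background stay open. Without any 1 of the 4 arrays of 200 min the count was at least 580, which argues against a single 200 min array. It was 344 without 180 min replicate 3 and 373 without the 180 min repeat pair. Steady progress from 180 to 360 min would leave few positions beyond both. By test 189 of the 707 lay beyond both, 140 to 387 when single 200 min arrays were left out (387 without replicate 3). Both tests use the same 200 min samples, so an array effect at 200 min would also give such positions. How many steady progress would give was not simulated, so it is not excluded. A separate batch or treatment of the 200 min arrays cannot be told apart from time, because the labels give no batch; their blank spots averaged 15.3% against 9.15% elsewhere, but single arrays ranged from 8.91% to 21.8%. A true change of the cells within 20 min also stays open, since all of the 200 min arrays belong to 1 time.

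Weak positions differed between arrays of 1 time, and which times stood out depended on the class of position. At 200 min the medians of the dim positions were −0.02, −0.40, 0.60 and −1.13 on replicates 1 to 4, a range of 1.73, which argues against a shared change of RNA; at 60 min they were −0.29, 0.58 and 0.11, and at 180, 360 and 720 min they lay within −0.05 to 0.08, 0.09 to 0.33 and 0.19 to 0.49. Near-background positions had a median of 1.45 on 60 min replicate 1 and 0.18 on replicate 2, which was counted as the same sample, and their medians also spread at 180 min (−0.03 to 0.36), 200 min (0.65 to 1.27), 360 min (−0.07 to 0.80) and 720 min (−0.32 to 0.42). If the 60 min pair is 1 sample, that difference of 1.27, against 0.0773 and 0.0748 in the repeat pairs of 180 and 360 min, argues against a change of RNA there. That the pair is 1 sample was inferred from bright positions only, so a difference of RNA between the 2 arrays stays open. Near-background positions were positive on all 4 arrays of 200 min, with 0.65 as the lowest median, and an offset between the channels may account for this, but channel intensities were not used here and a change of RNA stays open.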

How the results depend on the processing

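Alternatives with bright positions, positions not near background, single copies, separately centred copies and spots off small whole-number ratios were chosen after seeing the data. So were the fits without the 200 min arrays and without both arrays of a repeat pair. The 16 separate arrays were the count fixed in advance, and the remaining alternatives were also fixed before. The cause of a shift was not tested unless stated. Tests of the gene lists (camera, fry, estimated correlation, block) and of the direction were not run because the sources used here give the positions no gene names. With a log2 size of at least 1 asked in addition, which only narrows the calls, counts were 1, 16, 651, 250 and 441 at 60, 180, 200, 360 and 720 min, 304, 183, 19 and 395 for 200 against 180, 360 against 180, 720 against 360 and 720 against 60 min, 591 among times and 727 at any time. Scaling arrays to a common spread gave 644 at 60 min, 911 at 180 min, 12 for 180 against 60 min and 0 for 720 against 360 min (116 at an unadjusted p under 0.05). Values as deposited gave 4 for 180 against 60 min. They also turned the balance of signs at 60 min to 7 positive and 3 negative. Positions on all 16 arrays gave 22, 81 and 1 for 60 min, 180 min and their difference, and the median of copies gave 1 for that difference.

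The numbers were not taken to pair the samples, but a link between some arrays stays open. Over 30 pairs with the same number the lowest correlation of deviations was −0.27 and the median 0.0958, against −0.0543 over 72 pairs with different numbers. It was over 0.1 in 8 of 10 pairs of number 3, 5 of 10 of number 1 and 2 of 10 of number 2, and in 20 of the 72, and 1 of the 15 arrays whose number recurs correlated best with its own number at every other time. With replicate number as a block (consensus correlation 0.115) the count for 180 against 60 min was 1, and no other count moved by over 1.5 times. With 16 separate arrays counts were 558 and 429 at 60 and 180 min, 6 for their difference, 1139 for 200 against 180 min, 984 for 360 against 180 min and 169 for 720 against 360 min. With the block as well they were 577, 446, 6, 1219, 1057 and 222, and 1997 among times. More samples and hence more degrees of freedom enter these fits.

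Bright positions alone gave 41 and 103 at 60 and 180 min, 4 for their difference and 67 for 720 against 360 min. Copy 1 alone gave 0 (403 at an unadjusted p under 0.05) and 19 at 60 and 180 min, 451, 293, 0 (212 at an unadjusted p under 0.05) and 683 for 200 against 180, 360 against 180, 720 against 360 and 720 against 60 min, and 786 among times. Copy 2 alone gave 17 at 60 min, and copy 3 alone gave 129 and 82 at 60 and 180 min and 62 for 720 against 360 min. Fits of the compared times alone, which have fewer samples, gave 0 and 0 at 60 and 180 min (362 and 667 at an unadjusted p under 0.05), 1031 and 339 at 200 and 360 min, 350 and 164 for 200 and 360 against 180 min, and 0 for 720 against 360 min (455 at an unadjusted p under 0.05). With the 200 min arrays left out of the fit, counts were 20 at 60 min and 14 for 720 against 360 min.

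Leaving out single arrays or repeat pairs gave 0 to 22 at 60 min, 4 to 61 at 180 min, 1731 to 2184 at 200 min, 547 to 1134 at 360 min and 1378 to 1518 at 720 min. The differences ranged from 0 to 3 for 180 against 60 min, 344 to 952 for 200 against 180 min, 245 to 538 for 360 against 180 min, 0 to 36 for 720 against 360 min and 690 to 1158 for 720 against 60 min. The F tests gave 992 to 1684 among times and 1867 to 2428 at any time. A lone remaining sample was assumed to vary like the other times.

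Of 371 values of the 4 named positions under alternatives, 358 kept their sign and their side of the threshold, 3 lost a call (P3228 at 360 min with copy 1, without replicate 3 and without the repeat pair), 2 had too few values to be tested (P3166 at 720 min and P3672 at 60 min, with copy 3) and 8 changed sign, all of these at 60 min where none passed. P3166 at 60 min was 0.045 on a common scale, 0.774 with copy 1 and 0.011 without small whole-number ratios, and leaving out arrays gave −0.557 to 0.429, with 0.397 without replicate 2. P3672 was −0.023 with copy 2. Leaving out arrays gave −0.062 to 0.577 at P2056 and −0.310 to 0.052 at P3228. Of 226 correlations between times, 219 moved by less than the spread between arrays and 0 changed sign. The 7 that moved were 60 with 180, 360 and 720 min under copy 3 (0.573, 0.106 and 0.033), 60 with 180 min without 60 min replicate 3 (0.629), 180 with 200 and 720 min without the 180 min repeat pair (0.312 and 0.275) and 180 with 360 min without the 360 min repeat pair (0.399). Weak signal limits what can be said of the 455 positions near background.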

Other observations

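The tests of neighbouring positions were chosen after the pattern was seen, and the sets of positions described here were chosen by their calls.

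Positions called at 180 min were followed to 720 min. Of 20 bright positions with a positive call at 180 min, 16 were positive and 2 negative by test at 720 min, and their median log2 ratio was 0.96 at 180 min and 1.06 at 720 min. Of 32 with a negative call, 19 were negative and 7 positive by test at 720 min, and the median was −0.63 at 180 min and −0.44 at 720 min. As a share of the 52 calls at 180 min, 67.3% had the same sign at 720 min, against a mean of 64.0% (51.3% to 79.5% over 20 draws) for simulated unchanged samples that share a 0 min RNA; their lists differed in length, with means of 76.8 calls at 180 min and 265 at 720 min against 52 and 1702, so whether the agreement exceeds no change stays open. The share with the same sign at 360 min was 69.2%, against a simulated mean of 32.5% (9.72% to 44.8%). The simulated lists at 360 min were far shorter, with a mean of 73.7 calls against 1093, so this excess stays open too. At 60 min the medians of the 2 sets called at 180 min were 0.33 and −0.43.

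A set of 181 bright positions lay beyond both 180 and 360 min at 200 min by test, 87 with a higher and 94 with a lower log2 ratio. The higher ones had medians of −0.03 at 180 min, 1.15 at 200 min, 0.18 at 360 min and 0.31 at 720 min. The lower ones had medians of −0.02, −1.50, −0.33 and −0.68 in the same order. At 720 min 107 of the 181 were called with the sign of their change at 200 min and 22 with the opposite sign.

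Large ratios had a different make-up at different times. Among spots with ratios between 32-fold and 128-fold in size, 30 of 40 at 60 min and 21 of 21 at 180 min were whole numbers within 0.0005 on the log2 scale, against 3.35% and 2.81% by chance. At 200 min 122 of 225 were whole numbers, at 360 min 1 of 49 and at 720 min 11 of 56, with 4.16%, 3.99% and 3.97% by chance. Ratios this large cannot be flagged by the grouping by brightness. A weaker channel of 1 unit would give whole numbers. Their share exceeded chance at 60, 180, 200 and 720 min. At 360 min it did not, which argues against a weaker channel of 1 unit for the spots counted there. Other small values of the weaker channel were not tested, and channel intensities were not used here.

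Positions at fixed distances along the spot numbers varied together in the means of 360 and 720 min. Of 2600 distances, 2048 gave the highest correlation between different copies (0.22), 6 rows gave 0.21 and 512 rows 0.19, against a median near 0 (−0.0046). At 2048 rows the correlation between different copies was 0.988 of that within a copy. A local artefact on the slide need not link positions that far apart, so this ratio cannot decide. At 1, 2 and 3 rows the correlation within a copy was 0.147, 0.0738 and 0.0673, against 0.134, 0.0609 and 0.0548 between copies. Most of it was thus shared between copies, and a part from a local artefact stays open. A block of neighbouring rows is argued against as the whole cause because 2048 rows, far apart in the spot order, lay 6.06 SDs above the median distance; the correlations of 0.134, 0.0609, 0.0548, 0.102 and 0.104 at 1 to 5 rows leave a part from near rows open. A print order that keeps genomic neighbours, such as genes of 1 operon, at these distances may account for the pattern, with 0.212 at 6 rows as the value to explain, but no layout table was used here and this stays a hypothesis.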
